A study of Danio rerio with 2 samples.

How the data were processed

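Gene expression was measured in cardiac ventricles of 8-month-old zebrafish of 2 genotypes, vegfaa-/- and vegfaa+/+. Per the series design, each sample was a pool of 4 hearts, and each genotype was represented by 1 pool and 1 array. Per the labels' protocols, total RNA was isolated with a column kit, amplified from an oligo-dT primer into cRNA and labelled with cyanine 3. The injury state of the hearts and the part of vegfaa that the allele changes are not given in the sources used here.

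The authors deposited the scanner output of both 1-colour Agilent arrays, which lay on the same slide, in linear intensity units. Per the file headers, the images were read with Agilent Feature Extraction 11.5.1.1, and the probes were annotated on the Zv9 build of the zebrafish genome. The processed signal in these files is the intensity of a spot after background subtraction and detrending within the array, per the file headers, with no normalization between arrays. The authors also deposited a table of 1 value per probe for each array. From its values, it holds linear intensities on which the 2 arrays share 1 distribution, with a median of 207.242 in both columns, and each column correlated across probes with its own array's log2 signals at r = 0.9999. The table was therefore taken as quantile normalized, although the sources used here do not state the method, and it served as an alternative. The software's flags for signal well above background and for outlier spots, held in the same deposited files and coded 0 or 1, were used as other values.

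Each array carried 61657 spots other than controls, with 60022 probe names and 52814 distinct probe sequences. Of these spots, 92.2% were well above background on the vegfaa-/- array and 91.5% on the vegfaa+/+ array. None was saturated, and 12 and 9 were outliers and were left out. The median processed signal was 205.4 and 230.0, and the 75th percentile was 767 and 851. The local background of the vegfaa+/+ array was higher in its right part, with a median of 39 against 27 in its left part, while the median log2 difference between the arrays was -0.0019 there and -0.0074 on the left.

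For the main values, each array's 75th percentile of the processed signal was subtracted on the log2 scale. Spots of one sequence within a gene were averaged, and a gene's difference, vegfaa-/- minus vegfaa+/+, was the median over its probes well above background on at least 1 array. A gene counted as higher or lower if it was well above background on both arrays, at least 2-fold apart, and all its usable probes went the same way. A gene with 1 usable probe meets the last condition by construction. A second count used 4-fold. For a gene well above background on 1 array only, a lower bound of the fold was computed against the higher of the dim probe's own value and the lowest signal among single spots well above background on that array. No fold is given where this bound is under 1. Gene names were those of the array files. Of 42870 names, 21739 were transcript or prediction identifiers without a gene symbol, 15228 were current symbols, 2573 were older symbols updated through the RefSeq gene table of assembly GRCz12tu, and 3330 were kept as in the file. No coordinate was taken from that table. Sequences that matched several genes numbered 254.

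With 1 pool per genotype, no test between genotypes was possible, and no p-value, standard error or count of significant genes was computed. Differences have no replicate check. The noise of the measurement was described by probes of one gene. Across 7806 genes with at least 2 probes, a random pair of probes correlated at Pearson r = 0.465 and Spearman rho = 0.437, which is across genes and not across samples. The technical SD of a probe's difference from such pairs was 0.42 on the log2 scale, or 0.26 with a robust estimate. The same technical SD, from probes printed with the same sequence under other names, was 0.146. The number of arrays limits the precision.

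The 43 gene lists covered the VEGF pathway, cell types of the heart, signalling, metabolism, stress and tissues that a dissection could carry along. For each list, the median difference was taken over its measured genes, those well above background on both arrays. It was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries only. A 95% interval was drawn from 2000 bootstrap samples of the list's genes and covers the spread between genes, not between animals. Lists below the 2.5 or above the 97.5 percentile are called outside the random range. About 1.08 of 43 lists of randomly drawn genes would fall beyond each of these limits. Genes of one list can vary together, and some genes, such as ddit4, belong to more than 1 list. This is therefore not the number to be awaited between 2 pools of one genotype. The lists, the size rule, the alternatives and the rule for named genes were fixed before the data were examined. The text names measured VEGF genes. It names the 12 highest and 12 lowest genes with a curated symbol that were well above background on both arrays in every usable probe, had probes of the same sign, and were at least 2-fold apart in the same direction under every normalization of the scanner files. It also names the 5 genes per direction with the largest bound, and from each list up to 4 genes at least 2-fold apart or otherwise the 2 brightest. A few genes outside this rule are marked as chosen after their values were seen.

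Alternatives were quantile and median scaling, cyclic loess, normexp background correction with an offset of 50 followed by quantile normalization (limma 3.58.1 in R 4.3.3), filters on dim probes, outlier spots kept, the brightest probe or the mean of probes, the authors' deposited table, 4-fold, no required agreement of probes, and genes with at least 2 usable probes. After the data were seen, 4 more were added, which left out probes with a run of at least 7 alternating G and T bases, drew random lists from curated symbols, kept only list members with a signal of at least 100, or subtracted the median of curated genes. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The rules were tested on simulated data made from the vegfaa+/+ array over 19433 genes. Independent normal noise with an SD of 0.42 was added to each probe. For the comparison of vegfaa-/- with vegfaa+/+, 94 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were recovered. Of 19245 unchanged genes 219 passed the 2-fold rule, and 6 of 100 unshifted lists lay outside the random range. The simulation held no variation between pools, so these counts give no rate of false calls between 2 pools of one genotype.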

Results

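Ventricles of vegfaa-/- and vegfaa+/+ zebrafish were compared on whole-transcriptome arrays; vegfaa is one of the zebrafish genes for vascular endothelial growth factor A. The series concerns the growth of vessels into injured tissue and its part in heart regeneration. Each genotype was represented by 1 pool of 4 hearts from 8-month-old fish, so every value below is a difference between 2 pools and has no replicate error. Differences are log2 values of the vegfaa-/- pool minus the vegfaa+/+ pool after scaling to each array's 75th percentile, and positions are transcript coordinates on Zv9 as given in the array files, which do not state exons. The arrays correlated at r = 0.971 across 49945 probes above background on both.

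The vegfaa transcript itself was detected in both pools and was not lower in the mutant pool. The single vegfaa probe (chromosome 16, 4642220 to 4672554) read 1141 in the vegfaa-/- pool and 896 in the vegfaa+/+ pool, a difference of 0.50 on the log2 scale. That lies close to the technical SD of 0.42 for one probe. Because the changed part of the allele is not given in the sources used here, this probe cannot check the genotype. The paralog vegfab (chromosome 4, 5441937 to 5471073) differed by 0.66, with its 4 probes between 0.63 and 0.99. The receptor gene flt1, whose product binds VEGF and limits its signalling (chromosome 24, 22358758 to 22416767), was 2.39-fold higher in the mutant pool, with both of its probes on the same side. Of the 13 measured VEGF ligand and receptor genes, flt1 alone was at least 2-fold apart, 11 lay above 0, and the median was 0.45 (95% interval over genes 0.15 to 0.50), at the 99.97 percentile of random lists. The receptors kdrl and flt4 each differed by 0.45, kdr by 0.15, and the ligands vegfc by 0.49 and vegfd by 0.46. The co-receptors read 0.63 for nrp2b, 0.23 for nrp2a, 0.01 for nrp1a and -0.10 for nrp1b, and the dim vegfbb read -0.71. Both nrp1a and nrp1b had probes of opposite sign.

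Among 19445 named genes above background on both arrays, 508 were at least 2-fold higher and 896 at least 2-fold lower in the vegfaa-/- pool, together 7.2%. At 4-fold the counts were 77 and 106. Without probes that carry runs of alternating G and T, described below, 506 genes were higher and 721 lower among 19020. With normexp background correction the counts were 250 and 350. Of 472 genes with several probes whose median was at least 2-fold apart, 417 (88.3%) had all probes on the same side. The median difference was 0.03 over all genes, 0.06 over genes with curated symbols and -0.11 over genes named after genomic clones.

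The genes furthest above the wild-type pool included both ptgdsb genes, which encode lipocalin-type prostaglandin D2 synthases. ptgdsb.1 (chromosome 24, 17576415 to 17578479) was 40.5-fold higher, and its neighbour ptgdsb.2 (17570618 to 17572497) was 33.5-fold higher. The pyruvate kinase gene pkmb (chromosome 25, 30026828 to 30180180) was 30.6-fold higher, with 2 probes at 4.90 and 4.97. The glycogen-targeting phosphatase subunit gene ppp1r3aa was 30.4-fold higher, hhatlb 17.6-fold and the mucin gene muc5ac 16.8-fold. The smooth muscle gene tagln (chromosome 15, 542638 to 550075) was 15.2-fold higher at a signal of 17145 against 1247. The MHC genes mhc2dab and mhc1uba followed, at 12.1-fold and at 3.59 on the log2 scale. The next genes were crtac1a at 11.9-fold, cbln4 at 9.91-fold and the MAP kinase phosphatase gene dusp2 at 9.19-fold.

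In the opposite direction, lin7b, which encodes a cell polarity scaffold (chromosome 3, 32070869 to 32081685), was 24.8-fold lower in the mutant pool, at a signal of 12 against 326. The thymosin beta gene tmsb was 10.5-fold lower, the neuronal nitric oxide synthase gene nos1 9.62-fold and krcp 9.27-fold. tyms, which encodes thymidylate synthase (chromosome 7, 75222916 to 75229200), was 8.43-fold lower, dnase1l4.1 8.25-fold and dcdc2b 7.51-fold. The mutant signals of lin7b, krcp and dcdc2b were 11.9, 11.6 and 13.9. They lay near 10.4, the lowest signal well above background on that array, so their folds are imprecise. ndrg3a (chromosome 11, 25998078 to 26072620) was 7.80-fold lower, with 3 probes between -3.47 and -2.74. The adult alpha globin gene hbaa2 was 6.88-fold lower at 5540 against 42280, followed by atp1b1b at 6.71-fold, ube2t at 6.59-fold and lrrc3cb at 6.36-fold.

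**Figure D1:**
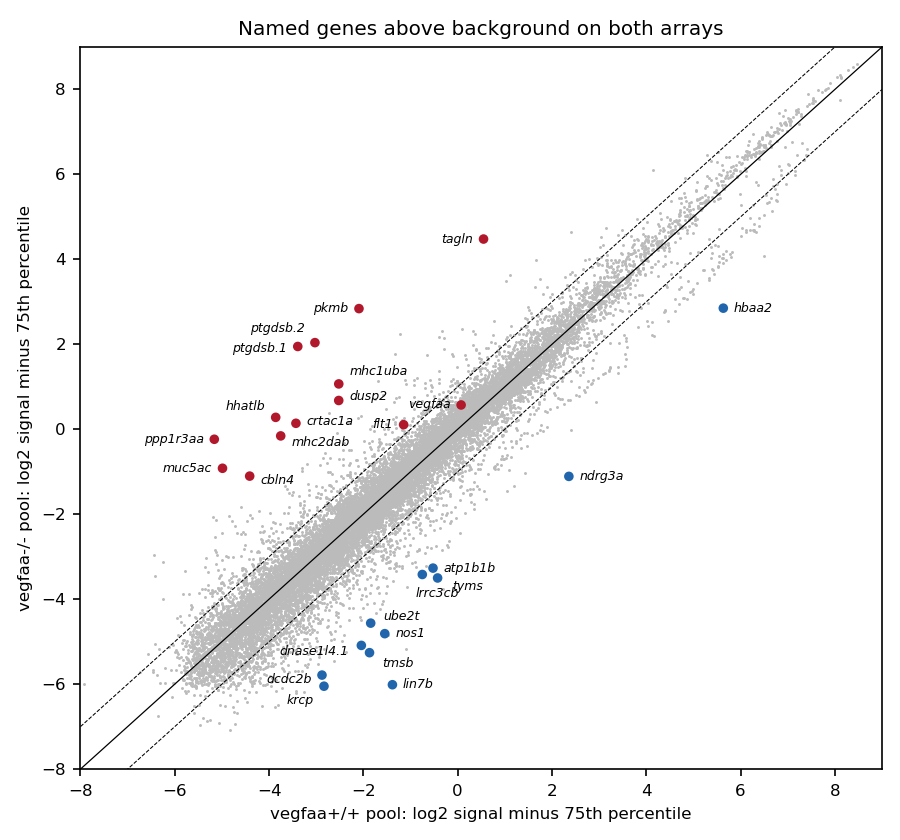
Each grey point is a named gene above background on both arrays, with its log2 signal minus the array's 75th percentile in the vegfaa+/+ pool on the x axis and in the vegfaa-/- pool on the y axis. The solid line marks equal values and the dashed lines a 2-fold difference, red points are vegfaa, flt1 and the 12 highest genes, and blue points are the 12 lowest, from lin7b at -4.63 to lrrc3cb at -2.67.

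Some genes were above background on 1 array only, 379 in the mutant pool and 241 in the wild-type pool, and have at most a bound. tcta (chromosome 6, 42947326 to 42950632) was at least 80.9-fold higher in the mutant pool. ankrd1a, a cardiac ankyrin repeat gene that responds to stretch and stress (chromosome 17, 23292799 to 23299763), was at least 40.3-fold higher, at 534 on the mutant array. The bounds were 26.4-fold for vgll2b, a cofactor of TEAD transcription factors, 15.1-fold for bcan and 12.5-fold for the follistatin-like gene fstl1a. Above background in the wild-type pool only, the collagen IV gene col4a6 (chromosome 7, 52375619 to 52557318) was at least 44.8-fold lower in the mutant pool and herc56.3 at least 8.32-fold lower. The bounds were 7.92-fold for tcf19l, 7.61-fold for ercc6l and 7.26-fold for sox8b.

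Endothelial marker genes went both ways around a median near 0. Of 29 endothelial genes 18 lay above 0 and 11 below, none was 2-fold apart, and their median of 0.10 lay at the 63.4 percentile. The brightest of them, aqp8a.1 and fli1rs, differed by -0.02 and 0.06, and the outermost, s1pr1 and vwf, named after their values were seen, by 0.91 and -0.87. The 3 probes of vwf disagreed in sign, from -1.09 to 0.09. The 12 venous and lymphatic genes had a median of -0.10 at the 17.7 percentile, with prox1a at 0.30. The 12 endocardial genes had a median of 0.13 at the 72.9 percentile, with nppc, encoding C-type natriuretic peptide, 3.03-fold higher. Of the 18 arterial and Notch genes 1 was higher and 1 lower, her9 at 1.03 and her6 at -1.09, and the median was 0.24 at the 96.8 percentile, or 97.55 after cyclic loess. Angiogenic signals other than VEGF were higher as a list, with a median of 0.48 (0.19 to 0.87) above all random lists, and 5 of 22 genes were at least 2-fold higher. They included the chemokine gene cxcl12b at 4.23-fold, adm2b at 2.64-fold and adma, encoding adrenomedullin, at 2.28-fold, whereas the apelin receptor gene aplnra was 2.59-fold lower. This median was 0.29 with normexp background correction.

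Smooth muscle and pericyte genes were higher in the mutant pool. Their median was 0.35 (0.22 to 1.06) at the 99.2 percentile, 12 of 13 lay above 0, and 4 were at least 2-fold higher. Besides tagln, the calponin gene cnn1b was 3.29-fold, rgs5b 2.27-fold and acta2, encoding smooth muscle actin, 2.09-fold higher. Genes of fibroblasts and extracellular matrix had a median of -0.17 (-0.30 to 0.14) at the 0.55 percentile, with 2 of 35 higher and 1 lower. Those were col12a1b at 1.19, loxl2a at 1.05 and mmp14b at -1.67, and the mmp14b probe carries an alternating GT run of 13 bases. Without such probes the list median was -0.11. The 8 outflow tract genes had a median of -0.13 at the 17.5 percentile, with the Notch ligand gene dla at -1.14, and the 10 epicardial genes had a median of 0.02 at the 38.9 percentile, with krt18a.1 at 0.69 and krt8 at 0.02.

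Genes of the cardiomyocyte sarcomere lay within the random range. Their median was 0.15 at the 56.8 percentile over 21 genes, and it was -0.07 after cyclic loess. One of them was lower, the ventricular myosin heavy chain probe that the array files call vmhc and the current table myh7, at -1.23. The 6 atrial genes had a median of -0.16 at the 7.88 percentile, with the troponin C gene tnnc1b 3.37-fold lower. Of 15 cardiac stress and embryonic programme genes above background on both arrays, xirp2a, encoding an actin-binding protein of intercalated discs, was 3.38-fold higher. The transcription factor gene tbx5a (chromosome 5, 75451438 to 75476894) was 2.81-fold lower. The list median was 0.23 at the 91.7 percentile. This median leaves out ankrd1a, a member of the list above background in the mutant pool only and at least 40.3-fold higher there. The 16 genes of calcium handling and conduction had a median of 0.12 at the 69.1 percentile and none was 2-fold apart. Their brightest members were atp2a2a at -0.02, with probes of opposite sign, and kcnh6a at -0.79, whose probe carries a GT run of 13 bases. Regeneration mitogens and their receptors were higher as a list, with a median of 0.26 (0.06 to 0.52) at the 99.6 percentile and 4 of 24 genes at least 2-fold higher. These were the neuregulin gene nrg1 at 2.31-fold, ccn2a at 2.20-fold, igf1rb at 2.14-fold and igf2b, on a probe with a GT run of 7 bases, at 2.06-fold. nrg1 was dim, with a wild-type signal of 27, and differed by 0.34 in its brightest probe. TGF-beta and BMP genes went both ways, 2 higher and 3 lower of 36, with id4 at -1.64, bmp2a at -1.30, id1 at -1.21 and nog1 at 1.26, and a median of 0.16 at the 95.3 percentile. The nog1 value was 0.19 in its brightest probe.

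Hypoxia-responsive and glycolytic genes were higher in the mutant pool. These lists share members by definition, among them hk2, pgk1 and ldha, so their shifts are not independent. The hypoxia list had a median of 0.31 (0.23 to 0.54) at the 99.94 percentile, 31 of 35 genes lay above 0, and 5 were at least 2-fold higher. The prolyl hydroxylase gene egln3 (chromosome 17, 9776820 to 9801699) was 3.37-fold, ddit4 3.25-fold and pfkfb3, encoding a regulator of glycolytic flux, 2.75-fold higher. The ddit4 value was 0.80 in its brightest probe. pfkfb4b was 3.34-fold lower, on a probe with a GT run of 14 bases. Of 33 glycolytic genes 26 lay above 0, and the median was 0.31 (0.13 to 0.58) at the 99.9 percentile. Besides pkmb, the isomerase gene gpib was 2.18-fold and the aldolase gene aldocb, on a probe with a GT run of 7 bases, 2.12-fold higher. Oxidative phosphorylation genes were above 0 in 65 of 70 cases with a median of 0.25 (0.21 to 0.32) at the 99.5 percentile. The subunit genes ndufa4b and cox6b1 were 2.24-fold and 2.01-fold higher. The median of this list was 0.10 after cyclic loess, and its percentile was 97.25 without GT-run probes. The 31 fatty acid oxidation genes had a median of 0.12 at the 60.5 percentile, with the dim fabp1b.1 at 1.27 from probes at 2.42 and 0.13. The lower value came from its brightest probe, the only one well above background on both arrays.

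Cell cycle genes were lower in the mutant pool throughout. All 33 measured on both arrays lay below 0, 19 were at least 2-fold lower and none higher, and the median of -1.57 (-1.82 to -1.05) was below every random list. The replication licensing genes mcm4 (chromosome 24, 37031305 to 37056313), mcm6 and mcm2 were 5.87-fold, 5.69-fold and 5.45-fold lower, alongside tyms. These genes were of low to moderate brightness, with a median wild-type signal of 238, and with normexp background correction the median was -0.57 and kif20a lay above 0. The probes of ccne2 and rrm1, named after their values were seen, carry GT runs of 18 and 14 bases, and without such probes the median was -1.67. Red blood cell genes were lower as well, with a median of -0.54 (-1.19 to -0.26) below every random list and 5 of 16 at least 2-fold lower. The adult beta globin gene hbba2 was 5.35-fold, the carbonic anhydrase gene cahz 2.64-fold and the anion exchanger gene slc4a1a 2.31-fold lower, in addition to hbaa2. The erythroid transcription factor genes gata1a and klf1, named here after their values were seen, read -0.89 and 0.64.

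**Figure D2:**
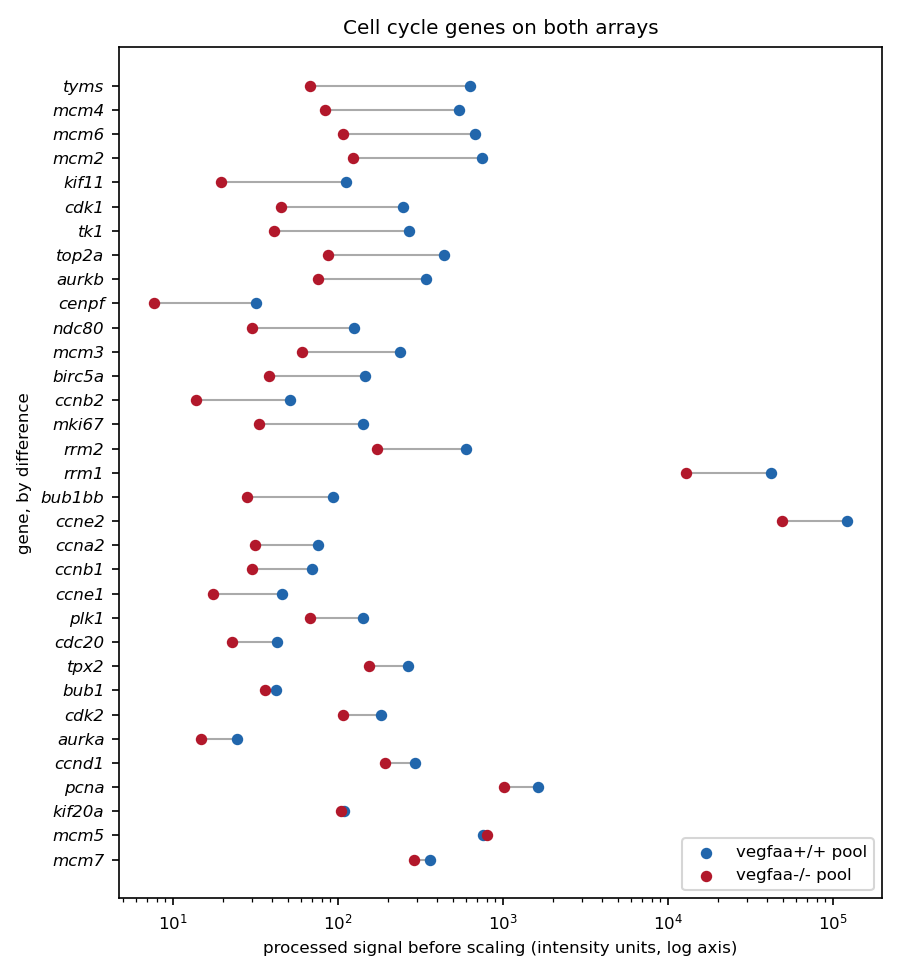
Processed signal in intensity units before scaling, on a log axis, for the 33 cell cycle genes above background on both arrays, in the vegfaa+/+ pool (blue) and the vegfaa-/- pool (red), sorted by the difference after scaling. tyms shows the widest gap with 68 against 634, and mcm7 at the bottom has the smallest difference after scaling, -0.06 on the log2 scale.

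Transcripts of the early response to stimulation were higher in the mutant pool. The immediate early list had a median of 0.46 (0.28 to 0.69) above all random lists, and 23 of 27 genes lay above 0. Of these genes 6 were at least 2-fold higher, among them dusp2, the nuclear receptor gene nr4a3 (chromosome 16, 29573622 to 29597577) at 7.10-fold, atf3 at 4.25-fold and fosl2 at 2.38-fold. fosab, named after its values were seen, was the 1 gene at least 2-fold lower, at -1.13. Glucocorticoid-responsive genes had a median of 0.49 (0.03 to 1.04) above all random lists, with 6 of 17 at least 2-fold higher. zbtb16b (chromosome 15, 17197147 to 17305080) was 5.18-fold, the co-chaperone gene fkbp5 2.40-fold and zbtb16a, where 1 of 2 probes carries a GT run of 7 bases, 2.26-fold higher. Cytokine and NF-kB feedback genes had a median of 0.25 (-0.22 to 0.60) at the 98.4 percentile, with socs3a, a feedback inhibitor of cytokine signalling, 4.70-fold higher at 19096 against 4502, and ccl25b 3.92-fold higher. Their percentile was 96.4 with normexp background correction. Heat shock and unfolded protein genes had a median of 0.23 (0.03 to 0.41) at the 98.8 percentile, with 3 of 38 higher. These were the small heat shock gene cryabb at 3.57-fold, hspa4a at 2.22-fold and chac1 at 2.03-fold. atf4a read -1.07 on a probe with a GT run of 14 bases, and the percentile of the list was 96.2 among random lists of curated symbols. Clock genes, which follow the time of day, had a median of 0.07 at the 60.9 percentile over 33 genes. With 18 of them above 0 and 15 below, this median does not show whether the pools were sampled at the same time. nr1d2a was 2.95-fold higher, and cry5, whose probe carries a GT run of 16 bases, was 3.03-fold lower.

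Leukocyte lists were mixed and lay within the random range in the main analysis. Macrophage genes had a median of 0.21 at the 97.0 percentile, with lgals3bp.1 at 1.43, csf1ra, encoding a colony stimulating factor receptor, at 1.08, grna.2 at 1.02, or 0.88 in its brightest probe, and the chemokine gene ccl34b.1 at -1.49. Neutrophil and mast cell genes had a median of 0.24 at the 95.1 percentile, which was 99.17 and outside the random range with normexp background correction, with 3 of 13 higher, npsn at 1.46, lect2l at 1.43 and the myeloperoxidase gene mpx at 1.01. Lymphocyte genes had a median of 0.17 at the 95.4 percentile, with il7r 3.03-fold higher and cd79a, on a probe with a GT run of 8 bases, at -1.13. Thrombocyte genes had a median of -0.01 at the 33.3 percentile, with fgl2a at 0.11 and gp1bb at -0.73, where 1 of 2 probes carries a GT run. Interferon-responsive genes had a median of -0.03 at the 31.6 percentile, with 1 of 23 higher and 3 lower. mhc1uba (chromosome 19, 7695390 to 7723636) differed by 3.59, while the nearby immunoproteasome gene psmb9a (7742916 to 7744909) was 4.46-fold lower. The dim mxa was 2.82-fold lower, with its brighter probe at -0.23, and cmpk2 by -1.38 on a probe with a GT run of 10 bases. MHC class II genes had a median of 0.26 at the 86.7 percentile over 4 genes, of which mhc2dab was higher.

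The 45 genes of the proteasome list had a median of 0.05 at the 40.8 percentile, and the 3 that were at least 2-fold lower were psmb12 at -2.22, psmb9a at -2.16 and psmc3ip at -3.14. psmc3ip entered by its name and encodes a recombination factor, not a proteasome subunit. The 72 cytosolic ribosomal protein genes had a median of 0.23 at the 97.1 percentile with none 2-fold apart, rpl6 at 0.22 and rps2 at 0.16. This median was 0.05 after cyclic loess, and the percentile was 98.3 with normexp. The 18 housekeeping genes had a median of 0.19 at the 79.4 percentile, with gapdh at 0.59 and rpl8 at 0.14. The 16 factors of nonsense-mediated decay, the pathway that removes transcripts with early stop codons, had a median of 0.10 at the 69.6 percentile, with rbm8a at -0.10 and upf3b at -0.36.

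Lists of markers of tissues outside the ventricle had median wild-type signals of 64 to 361, and some of them differed between the pools. Skin and gill epithelium genes had a median of 0.30 (0.19 to 0.85) at the 99.3 percentile, with 4 of 16 at least 2-fold higher. The keratin genes cyt1 and krt97 were 5.23-fold and 4.95-fold higher and agr2, a gene of mucus-secreting cells, 4.72-fold higher, at signals of 104 to 203 in the mutant pool. The value of cyt1, which shares a probe sequence with another gene, was 0.28 in its brightest probe. The last of the 4, cyt1l, read 1.18 from probes at 0.31 and 2.05. Gonad genes had a median of 0.32 (-0.23 to 0.35) at the 99.7 percentile, no gene was 2-fold higher, gdf9 read -1.27, and the median wild-type signal was 64. This median was 0.13 with the brightest probe and 0.15 with normexp. Exocrine pancreas and gut genes had a median of -0.26 at the 5.16 percentile, or 2.01 with normexp, with 3 of 16 lower, ctrb.1 at -2.30 on a probe with a GT run of 7 bases, prss59.1 at -1.85 and ela2l at -1.18. Liver and yolk genes had a median of 0.03 at the 57.4 percentile, with the liver fatty acid binding protein gene fabp10a at 2.31, tfa at 1.15 and apoa4b.1 at -1.07. Skeletal muscle genes had a median of 0.00 at the 49.4 percentile, with myod1 at 1.38, myhz2 at 1.02, mylpfa at -1.41 and the dim tnni2b.2 3.99-fold lower. Neural genes had a median of -0.20 at the 8.98 percentile, with sox10, a gene of glia and neural crest, at -1.30, and the median was 0.01 without GT-run probes.

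**Figure D3:**
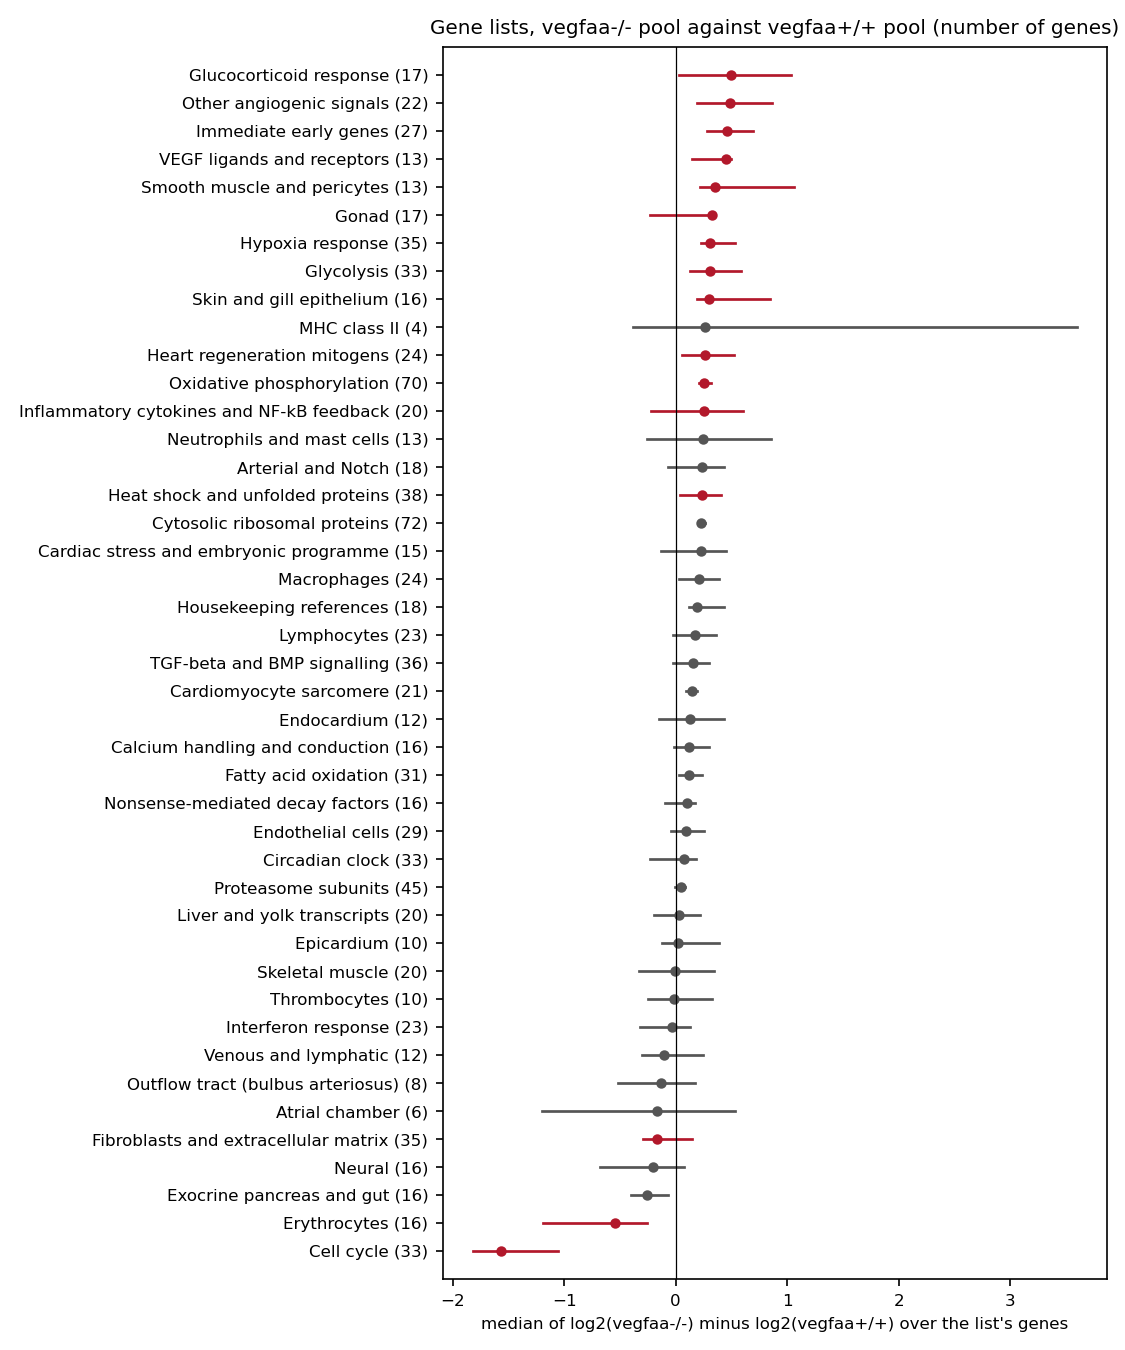
Points are list medians of log2 vegfaa-/- minus log2 vegfaa+/+ for the 43 gene lists and bars are 95% bootstrap intervals over genes, with the number of genes in brackets. The lists outside the random range are in red, 13 above its upper limit and 3 below its lower limit, and cell cycle genes stand apart at -1.57.

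Probes whose sequence holds a run of alternating G and T were lower in the mutant pool irrespective of the gene named. At runs of 3 bases or fewer, the median difference of 30057 probe sequences was 0.02 and 4.2% were at least 2-fold lower. At runs of 9 to 11 bases the median of 345 sequences was -1.15, and at runs of 12 or more the median of 254 was -1.66 with 91.7% at least 2-fold lower. Of the 896 named genes at least 2-fold lower, 192 carried a probe with a run of 7 bases or more, against 15 of the 508 higher.

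**Figure D4:**
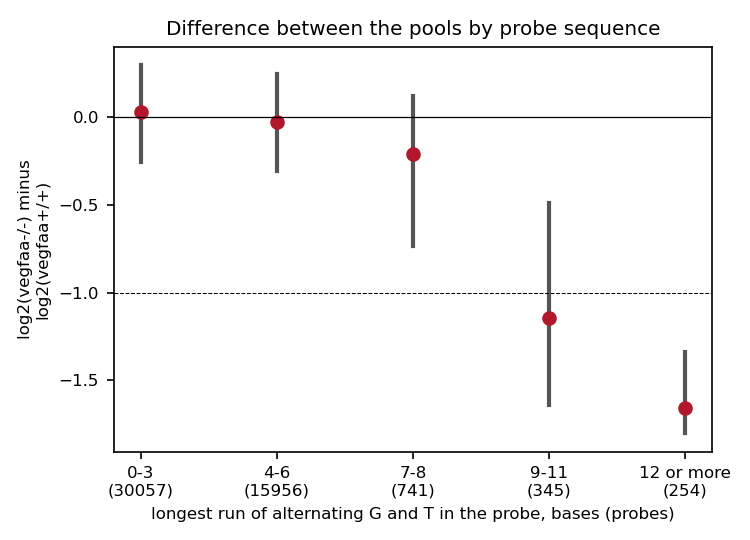
Log2 vegfaa-/- minus log2 vegfaa+/+ by the longest run of alternating G and T in the probe, over distinct probe sequences above background on both arrays, with the number of sequences in brackets. Points are medians and bars span the 25th to 75th percentile, and the median goes from 0.02 at runs of 3 or fewer to -1.66 at runs of 12 or more.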

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

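The comparison of genes and lists above covers named genes only. The correlation between the arrays and the medians by GT run also included probes of transcripts without a gene symbol. The test of intensity trend, the test of GT runs as the source of the cell cycle difference, the erythroid test, the count of pools per genotype and the cross-hybridisation test were chosen after the results they measure were seen. The cross-hybridisation test replaced 2 earlier versions, one that compared signal levels of different probes and one that took its control from other genes.

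Transcripts without a gene symbol were outside the main measurement, and more of them were lower than higher in the mutant pool. Of 19632 such transcripts above background on both arrays, 418 were at least 2-fold higher in the mutant pool and 1362 at least 2-fold lower. For named genes these counts were 508 and 896 of 19445. Probes with GT runs were kept in both. Of 429 above background in the mutant pool only, 52 were at least 2-fold above the limit of the wild-type array. Those above background in the wild-type pool only were not examined in this way.

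The lower level of cell cycle genes in the mutant pool had a median of -1.57 over 33 genes. An intensity-dependent trend between the arrays does not account for it, since the median was -1.61 (-1.78 to -0.96) after cyclic loess. Probes with GT runs do not account for it either, since the median without them was -1.67 (-1.89 to -0.93). A smaller number of dividing red blood cell precursors in the mutant pool is a candidate explanation that stayed undecided, because 6 early erythroid genes had a median of -0.34, with 4 of them below 0. The genotype, which may lower proliferation, and a difference between the pools other than genotype, such as the state of single fish, cannot be told apart with 1 pool per genotype.

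Probes with runs of alternating G and T were lower in the mutant pool by a median of -1.66 at runs of 12 or more. Lower expression of the genes they name does not account for this. In 98 genes that also had a probe without a run, the latter had a median of 0.11 (0.05 to 0.18), against -1.65 for the probes with a run. Cross-hybridisation of RNA that contains the complementary repeat is a candidate explanation that stayed undecided. Across these genes the 2 kinds of probe correlated at r = 0.13 (-0.04 to 0.31), and 2 probes without a run correlated at 0.28 in the 37 genes that had them, an interval (-0.11 to 0.62) too wide to set them apart. Over all probe sequences, the median signal in the vegfaa+/+ pool was 263 at runs of 3 bases or fewer. It was 1599 at runs of 9 to 11 and 32762 at 12 or more. Repeat-containing RNA would give such a rise, but the rise compares different probes and does not decide the question.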

How the results depend on the processing

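The alternatives that left out GT-run probes, used curated random lists, kept brighter list members or centred on curated genes were chosen after seeing the data. vegfaa stayed between 0.48 and 0.51 under the alternatives run for it, which did not include centring on curated genes. The median of all named genes moved by at most 0.04 on the log2 scale with another scaling. No named gene at least 2-fold apart and no list outside the random range changed sign under the alternatives run for it. The count of genes at least 2-fold higher was 508 and of genes lower 896. With normexp background correction followed by quantile normalization (normexp below) these became 250 and 350. Quantile normalization alone, of the processed signal, gave 574 and 769, so the quantile step does not account for that fall. The background correction and its offset were not run apart. The counts were 77 and 106 at 4-fold, and 175 and 242 among genes with at least 2 usable probes, a smaller set by construction. The cell cycle median was -0.57 with normexp, but stayed inside its interval over genes with quantile normalization alone. Whether the background correction or its offset raised it was not tested. The oxidative phosphorylation median of 0.25 became 0.33 with quantile normalization, 0.10 with cyclic loess, 0.33 with normexp, 0.36 with the authors' deposited values and 0.19 after subtracting the median of curated genes, and its percentile was 97.25 without GT-run probes. The gonad median of 0.32 became 0.40 with quantile normalization, 0.36 with cyclic loess and 0.40 with the deposited values. It fell to 0.13 with the brightest probe and 0.15 with normexp, both inside its interval over genes. The percentile of the inflammatory list was 96.39 with normexp and that of the heat shock list 96.24 among curated random lists. Some lists inside the random range came out of it. With normexp the percentile was 99.17 for neutrophils and mast cells, 98.3 for cytosolic ribosomal proteins and 2.01 for exocrine pancreas and gut, and with cyclic loess it was 97.55 for arterial and Notch genes. Among random lists not matched on expression it was 99.98 for ribosomal proteins and 1.08 for exocrine pancreas. The ribosomal median of 0.23 was 0.05 after cyclic loess. The cause was not tested for these. Of 1586 alternative values of single named genes, 102 moved by over 1 technical SD, 70 of them with normexp. Of 110 named genes at least 2-fold apart, 36 were under 2-fold with normexp, 9 without GT-run probes and 8 with the brightest probe. Signal over background limits dim genes such as nrg1 and the gonad list. No paired analysis was possible because each genotype has 1 sample and no test.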

Other observations

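The test of the chromosome segment around vegfaa was chosen after the values were seen. psmb8a and tap2a are also named here after their values were seen.

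Immune genes of the core MHC region on chromosome 19 differed in both directions within a short stretch of Zv9. mhc1uba (7695390 to 7723636) read 1609 in the vegfaa-/- pool and 148 in the vegfaa+/+ pool. Beside it the immunoproteasome genes psmb12 (7737759 to 7741992) and psmb9a (7742916 to 7744909) read -2.22 and -2.16 on the log2 scale, and the peptide transporter gene tap2a (7746873 to 7753954) read -1.35. The 2 probes of psmb8a (7728374 to 7767084) disagreed, at 0.20 and -2.58.

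Non-coding transcripts were not shifted alike. Of 723 probes for long intergenic RNAs, 19.2% were at least 2-fold lower and 2.1% higher in the mutant pool, with a median of -0.29 that was -0.28 without GT-run probes. Probes for ribosomal RNA had a median of -0.27 over 1716 sequences, whereas 211 for small nuclear and 232 for small nucleolar RNAs had medians of 0.32 and 0.29. The cRNA was amplified from an oligo-dT primer, and whether the signal of these classes follows their RNA level was not tested. Among predicted transcripts, 12 probes that share the sequence GGTCCAGGATCAACAT had a median of -3.47 (range -3.83 to -3.14) at a median signal of 8261 against 100927, and none of them names a gene.

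Genes at least 2-fold apart lay next to each other on the chromosomes more often than after shuffling. Among 18228 placed genes with GT-run probes left out, 87 pairs of neighbours with different name stems were both at least 2-fold apart, against a median of 71 after shuffling (90% range 59 to 84). Sequence variants or haplotypes that differ between the pools would give such pairs, and regulation of neighbours together would too. Of these pairs 69.0% went the same way, against a median of 51.4% after shuffling (90% range 41.7 to 61.2). Regulation of neighbours together would give such a share, and haplotypes stay open. Related genes with different name stems, such as those of different clones, still counted as pairs. The shuffle did not hold signal level or probe number fixed, so neither value settles the source. A chromosome segment inherited with the vegfaa allele is a further hypothesis. Within 5 Mb of vegfaa, 11 of 95 genes (11.6%) were at least 2-fold apart against 6.5% elsewhere, at the 91.7 percentile of windows of as many genes, which does not decide it.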
